A study of Hordeum vulgare and Hordeum vulgare
Serendipita vermifera and Hordeum vulgare
Bipolaris sorokiniana with 33 samples.

How the data were processed

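The series holds RNA sequencing of barley (Hordeum vulgare cv. Golden Promise, Hv), the root endophyte Serendipita vermifera (Sv) and the root pathogen Bipolaris sorokiniana (Bs), grown alone, together in soil, or on barley roots held in a split-root chamber. Per the labels' protocols, fungal mycelium was kept in soil in the dark for 2 days, either Sv alone, Bs alone or both mixed. Barley seedlings received Sv, Bs, both or distilled water, and roots were taken 6 days later from 6 plants per treatment. The labels call a root sample local where the sampled side carried the inoculum and systemic where the other side did. The 33 libraries form 11 groups of 3. These are Sv soil, Bs soil and Sv with Bs soil, and 8 root groups: mock, Sv local, Sv systemic, Bs local, Bs systemic, Sv local with Bs local (co-inoculated), Sv local with Bs systemic, and Bs local with Sv systemic. The labels do not say whether the 3 replicates of a group are separate plants or cultures, so p-values measure the spread between these samples, which may be technical. They also name natural soil in places and sterile soil in others, and give seedling ages of 4 and 7 days. Descriptions of Bs systemic replicates 2 and 3 name the same column, and the remaining column was taken as replicate 3. Mycelium RNA and root RNA were extracted with different kits per the labels, so any comparison of roots with soil also compares kits and harvest days.

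The deposited tables used here are 3, 1 per organism, each listing the genes of that organism. The submitters' processing notes name FastQC 0.11.4, Trimmomatic 0.36, TopHat2 2.1.0, HTSeq without a version and edgeR 3.15.1, with no genome builds. Per the file headers, the columns used here hold raw read counts per gene (counts), checked to be whole numbers. The deposited tables also hold a gene length column in nucleotides (unit other), which was not used, and annotation text for each gene. A further 270 per-sample columns of the tables, and tables that pair fungal gene identifiers with other identifiers, were not used here. A later barley gene table matched 0 of the 36957 barley identifiers, so no coordinates were used, and functions are those of the deposited annotation text.

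Differential expression was computed in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16, after TMM scaling and filterByExpr (minimum count 10, minimum total 15). P-values were adjusted by Benjamini-Hochberg and called at 0.05, which is the adjusted p meant throughout. Each organism was scaled on its own counts, so a change is relative to that organism's total. Levels are the CPM of edgeR, the gene's share of the organism's TMM-scaled library total, as mean ± SD of 3 libraries, and depend slightly on which libraries share a fit. Log2 fold changes carry ± SE, computed as the size of the change over the square root of F. Barley comparisons were contrasts in 1 fit of all 24 root libraries. Soil comparisons, and comparisons of roots with soil, used the 6 libraries compared, and fungal comparisons between roots used the 9 root libraries inoculated with that fungus. Where a group had 0 reads of a gene, the fold is a lower bound against a floor of 3 reads over the group, and where it had 1 to 3 reads no fold is given. These floors and the binomial intervals cover counting error alone.

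Genes were named by a rule with an adjusted p under 0.05. For the largest changes it also asked for 3 against 3 libraries not overlapping in CPM, a mean of at least 5 CPM in the higher group and informative annotation text. Text such as hypothetical or the like did not count as informative. The rule took the 6 largest changes in each direction, or 3 in each direction for smaller comparisons, and up to 2 called members of each gene list with the smallest p. Any other named gene is said to have been chosen after its values were seen. Each gene named as a largest change between 2 groups was therefore higher, or lower, in 3 of 3 libraries against 3 of 3. For list members and for the interaction the rule did not ask for this.

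Gene lists were patterns in the annotation text. For barley they covered defence proteins, WRKY factors, receptor kinases, NLR resistance proteins, class III peroxidases, glutathione transferases, phenylpropanoid and lignin enzymes, terpenoid synthesis, cytochromes P450, jasmonate, ethylene, nutrient transport, sugar transport, cell wall, photosynthesis (as a marker of shoot tissue), ribosomal proteins, histones, heat shock proteins and aquaporins. For the fungi they covered carbohydrate-active enzymes, fungal wall enzymes, effector-like secreted proteins, proteases, MFS and ABC transporters, nutrient transporters, secondary metabolism, cytochromes P450, redox and detoxification, heat shock, ribosomal proteins, histones, iron and siderophores, conidia and melanin, and zinc cluster factors. Lists with at least 5 tested members were tested with camera in limma 3.58.1, at its preset correlation of 0.01 and again with an estimated correlation. The photosynthesis list (46 genes), the fungal wall list in Bs (4 genes) and the conidia and melanin list in Sv (4 genes) had too few tested members and were not tested.

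Shares of reads per organism were compared with two-sided exact permutation tests, whose smallest possible p is 0.1 with 3 against 3 libraries, and 0.25 when replicate numbers are paired. Precision was tested on simulated data with 200 changed genes. The share of 2-fold changes called was 68% for barley genes in Bs local against mock, 48% and 34% for Sv and Bs in soil, 29% and 42% for Sv and Bs in roots, and 16% and 11% where roots were set against soil. For 4-fold changes it was 90%, 98%, 89%, 88%, 94%, 60% and 71% in that order. Between 1 and 8 unchanged genes were called per simulation, and with no change at all 2 for Sv in roots against soil and 0 otherwise. A shifted gene set ranked 1 of the tested sets, and 0 of 20 random sets were called.

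Depth differed by organism. Barley had 4131985 to 5250642 counted reads in each of the 24 root libraries. Root libraries inoculated with the fungus held 82311 to 256693 Sv reads and 107929 to 578376 Bs reads. In soil the totals were 15354738 to 17990809 Sv reads in Sv soil, 18590755 to 20787932 Bs reads in Bs soil, and 10534040 to 13558790 Sv and 4003564 to 5293997 Bs reads in the mixture. After filtering, 19693 barley genes, 3606 Sv genes and 4890 Bs genes were tested in roots.

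Groups, comparisons, gene lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0 with its Wald test, RLE scaling, no filter on low counts, a fit of only the compared groups, a fit of all libraries inoculated with the fungus, a block for replicate number, and each library left out in turn. An alternative without the genes that take reads in samples lacking the fungus was chosen after seeing the data. Counts of calls were also taken for the other splits of the libraries of each comparison. Figures were drawn with matplotlib 3.10.9. No reads were realigned, and barley counts were given for the root libraries only.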

Results

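Fungal reads were counted in all root libraries, and the libraries whose sampled side received a fungus stood far above the others. Bs reads made up 8.52 ± 3.34% of counted reads in Bs local roots (5.9 to 12.3%, n = 3) and 3.86 ± 1.49% in co-inoculated roots (2.25 to 5.2%, n = 3). The ratio of the means was 0.453, a log2 difference of -1.14, and the co-inoculated libraries were below the Bs local libraries in 3 of 3 against 3 of 3. A two-sided exact permutation test gave p = 0.1, the smallest this design allows, and pairing replicate numbers gave an exact p = 0.25, again the smallest possible. With Sv on the opposite side the Bs share was 5.63 ± 3.12% (3.37 to 9.19%), a ratio of 0.661 to Bs local roots, which did not exceed the spread between replicates (two-sided exact permutation p = 0.4, paired exact p = 0.5).

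Sv reads made up 4.01 ± 1.29% in Sv local roots (2.71 to 5.3%), 3.4 ± 1.82% in co-inoculated roots and 3.52 ± 1.25% with Bs on the opposite side, with n = 3 in each group. Neither ratio, 0.848 and 0.879, exceeded the spread between replicates (two-sided exact permutation p = 0.8 and 0.7, paired 1 and 0.75, smallest possible 0.1 and 0.25). Background in the 15 root libraries not inoculated with the fungus on the sampled side was 0.024 to 0.0416% for Sv and 0.0408 to 0.0816% for Bs, and mock roots held 0.0299 ± 0.00339% and 0.0646 ± 0.00694%. In the soil mixture 27.3 ± 5.38% of reads were Bs and 72.7 ± 5.38% Sv. Counting error within a library was small beside these differences, with an exact binomial interval of 12.25 to 12.31% around the highest Bs share, 12.28%.

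**Figure D1:**
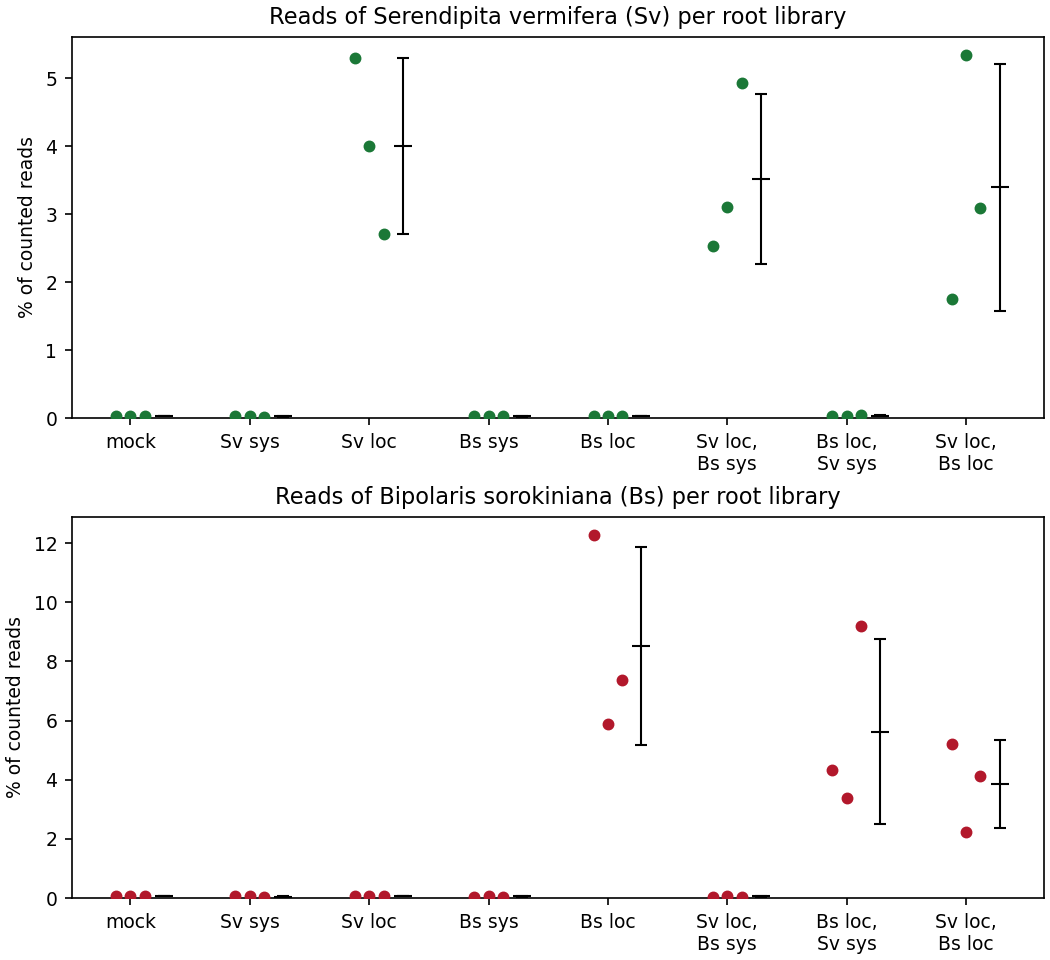
Percent of counted reads from Sv (top) and Bs (bottom) in each root library, by treatment group; points are libraries and bars the group mean ± SD of 3 libraries. The 3 co-inoculated libraries hold 2.25 to 5.2% Bs reads, all below the 3 Bs local libraries at 5.9 to 12.3%.

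Sv kept in soil with Bs raised a chitinase-family hydrolase, a chitin deacetylase, an extracellular metalloprotease and glutathione-dependent enzymes over Sv alone. A glycoside hydrolase of family 18, the chitinase family, rose by 3.77 ± 0.29 on the log2 scale (Sebve1_06375, 607 ± 226 against 44.5 ± 1.27 CPM, n = 3 each, adjusted p = 0.00123). A family 20 hydrolase, the family of hexosaminidases that release chitin monomers, rose by 2.27 ± 0.22 (Sebve1_04512), and a chitin deacetylase by 2.93 ± 0.37 (Sebve1_07811, 116 ± 63.4 against 15.1 ± 2.15 CPM). An extracellular metalloprotease rose from 247 ± 28.7 to 1360 ± 566 CPM (Sebve1_04060, log2 2.46 ± 0.30). Glutathione-dependent enzymes that detoxify or reduce peroxides rose as well, a glutathione transferase by 2.67 ± 0.45 (Sebve1_02355) and a glutathione peroxidase by 1.89 ± 0.34 (Sebve1_07049). The largest named increase was a gene related to short-chain dehydrogenases, at 231 ± 77.4 against 2.87 ± 0.753 CPM (Sebve1_11281, log2 6.33 ± 0.36, adjusted p = 0.000399). Increases of similar size in an mnn4-like gene (Sebve1_01089), a gcn5-related gene (Sebve1_02876) and a cell wall surface anchor gene (Sebve1_10581) had an SD above the mean in the mixture (213 ± 309, 191 ± 310 and 339 ± 540 CPM). The remaining 2 of the largest increases were an NAD(P)-binding protein (Sebve1_11277, log2 6.19 ± 0.72) and an oxidoreductase (Sebve1_07323, log2 5.96 ± 0.54). Without Sv soil replicate 2 or 3 the chitin deacetylase, the metalloprotease, the glutathione enzymes and the 3 genes with an SD above the mean lost their calls, and without replicate 2 Sebve1_11277 did.

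The largest named decreases of Sv in the mixture were smaller in fold than the largest increases. A gene annotated NADH-quinone oxidoreductase fell from 124 ± 67.9 to 16.2 ± 1.67 CPM (Sebve1_03076, log2 -2.93 ± 0.44). A peptidyl-prolyl isomerase, an enzyme of protein folding, fell from 418 ± 153 to 80.7 ± 51.6 CPM (Sebve1_10310, log2 -2.37 ± 0.49). A caspase-like peptidase of family C14 (Sebve1_10874, log2 -2.34 ± 0.40), a short-chain dehydrogenase (Sebve1_03570, log2 -2.37 ± 0.34), a P-loop protein (Sebve1_06827, log2 -2.02 ± 0.49) and an ankyrin protein (Sebve1_06588, log2 -2.02 ± 0.36) fell too. Of 13807 tested Sv genes, 619 rose and 417 fell, 466 and 307 of them by at least 1 on the log2 scale. The count rested on single libraries, that of the decreases most. Without Sv soil replicate 1 it was 202 (147 up and 55 down), without replicate 2 it was 28 (27 and 1) and without replicate 3 it was 30 (28 and 2). All 6 named decreases lost their calls without Sv soil replicate 2 or 3. Without replicate 1 of the mixture the count was 1569 (807 and 762), without its replicate 3 the decreases numbered 219, and DESeq2 called 2561 (1324 and 1237).

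In all, 8 Sv lists shifted upward in the mixture. Carbohydrate-active enzymes had 30 of 264 members up and 1 down (41 and 3 adjusted over the list alone, camera adjusted p = 0.00873). Proteases had 21 of 149 up and 5 down (38 and 9 adjusted over the list alone, adjusted p = 0.00255). MFS and ABC transporters had 17 of 128 up and 3 down (26 and 4 alone, adjusted p = 0.000631). Redox and detoxification had 7 of 68 up and 1 down (22 and 1 alone, adjusted p = 0.00255). The MFS transporter Sebve1_09720 rose from 14.7 ± 3.42 to 148 ± 52.4 CPM and the amino acid permease Sebve1_05659 from 303 ± 39.1 to 816 ± 252 CPM, a call lost without any 1 of the Sv soil replicates. Fungal wall enzymes (1 of 11 up, 4 adjusted over the list alone), nutrient transporters (4 of 44 up and 1 down, 7 and 1 alone) and cytochromes P450 (6 of 81 up, 9 alone) had an adjusted p = 0.00873 each. Histones had 0 of 13 called, 6 up alone and an adjusted p = 0.0259. With an estimated correlation each of these lists had an adjusted p = 0.433. Effector-like proteins (0 up and 1 down of 13), secondary metabolism (1 up of 12) and heat shock (2 up and 3 down of 51) were not called. Neither were ribosomal proteins (2 up of 62, 0 adjusted over the list alone), iron and siderophores (0 of 7) and zinc cluster factors (0 of 21, median 0.06, mean -0.06).

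Bs kept in soil with Sv raised a catalase and lowered peptide synthetases, while the secondary metabolism list as a whole was not called. Catalase, which breaks down hydrogen peroxide, rose from 6.64 ± 4.11 to 819 ± 180 CPM (Bipso1_04366, log2 6.95 ± 0.55, n = 3 each, adjusted p = 0.000691). Genes whose families handle reactive nitrogen and formaldehyde were among the 6 largest increases, a cytochrome P450 55A3, of the nitric oxide reductase family (Bipso1_04799, log2 7.26 ± 0.85), and an S-(hydroxymethyl)glutathione dehydrogenase (Bipso1_08391, 267 ± 156 against 1.36 ± 1.11 CPM, log2 7.61 ± 0.85). The others were a reticulon-like gene (Bipso1_04618, log2 7.50 ± 0.84), a WSC domain gene (Bipso1_07996, log2 7.06 ± 1.23) and a molybdopterin oxidoreductase (Bipso1_06117, log2 6.72 ± 0.44). Among the 6 largest decreases, an O-methyltransferase was at least 74.4-fold lower, with 0 reads against 16.3 ± 4.18 CPM (Bipso1_08023). The peptide synthetases, large enzymes that assemble peptides without a ribosome, were at least 44-fold lower (Bipso1_12079) and at 0.732 ± 0.121 against 98.5 ± 51.5 CPM (Bipso1_12059, log2 -7.06 ± 0.57). A fumonisin C-5 hydroxylase-like gene fell from 88.6 ± 91.9 to 0.312 ± 0.37 CPM (Bipso1_10117), a family 2 glycosyltransferase was at least 29.4-fold lower (Bipso1_10198), and a chitin-binding gene had 1 read in the mixture against 18.4 ± 13.9 CPM (Bipso1_10196).

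Other Bs genes in the mixture differed within their lists. A polyketide synthase rose from 136 ± 69 to 2000 ± 496 CPM (Bipso1_02104). A family 61 glycoside hydrolase, now known as a polysaccharide monooxygenase, rose from 15.3 ± 1.85 to 561 ± 270 CPM (Bipso1_07148), and the stress protein hsp12 from 136 ± 69.8 to 1710 ± 771 CPM (Bipso1_00021). Effector 74 fell from 406 ± 150 to 8.66 ± 8 CPM (Bipso1_04936) and carboxypeptidase A1 from 173 ± 92.1 to 5.04 ± 1.86 CPM (Bipso1_05912). An ammonium transporter (Bipso1_03691, log2 4.80 ± 0.51), an amino acid permease (Bipso1_11983, log2 5.20 ± 0.51) and a cytochrome P450 (Bipso1_05360, 147 ± 5.13 against 3.38 ± 1.43 CPM) rose. Of 10782 tested Bs genes, 2233 rose and 1904 fell, 1640 and 1069 by at least 1 on the log2 scale. The total of 4137 was 2419 (1476 up and 943 down) and 2315 (1432 and 883) without replicates 2 and 3 of the mixture. Of the reads in Sv soil, 0.455 ± 0.0454% were counted to Bs, and of those in Bs soil 0.197 ± 0.0575% to Sv. Without the genes that take such reads, an alternative chosen after seeing the data, 3 of the Bs calls and 4 of the Sv calls were lost.

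Ribosomal proteins were the Bs list with the smallest p in the mixture, with 58 of 81 down and 1 up (67 and 1 adjusted over the list alone, camera adjusted p = 9.22e-09, adjusted p = 0.401 with an estimated correlation). The 40S protein S5 fell by 1.25 on the log2 scale (Bipso1_11629, log2 -1.25 ± 0.20), and the exception was a gene annotated 40S S7 (Bipso1_10910, log2 5.19 ± 0.64). Proteases fell, with 54 of 173 down and 17 up (57 and 18 adjusted over the list alone, adjusted p = 0.00195). So did carbohydrate-active enzymes, with 86 of 323 down and 44 up (89 and 44 alone, adjusted p = 0.0315), and both had an adjusted p = 0.313 with an estimated correlation. MFS and ABC transporters (70 up and 32 down of 215, 75 and 35 alone, adjusted p = 0.0316) and cytochromes P450 (43 up and 22 down of 108, 44 and 24 alone, adjusted p = 0.0315) rose, each with an adjusted p = 0.401 with an estimated correlation. Redox and detoxification rose (28 up and 13 down of 77, 29 and 14 alone, adjusted p = 0.0315, and adjusted p = 0.313 with an estimated correlation), among them a heme peroxidase (Bipso1_08240, log2 2.97 ± 0.21). Conidia and melanin (4 up and 2 down of 15, with a conidiation factor down, Bipso1_07195, log2 -2.14 ± 0.33) and zinc cluster factors (27 up and 9 down of 98, adjusted p = 0.0683) were not called. Heat shock (20 up and 7 down of 51), histones (1 up and 4 down of 12) and iron and siderophores (1 up and 6 down of 20) were not called. Neither were effector-like proteins (5 up and 9 down of 21), nutrient transporters (16 up and 13 down of 72) and secondary metabolism (13 up and 16 down of 50).

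Sv on barley roots raised a xylanase, a cellulase and a hexose transporter and lowered HSP20 and HSP104 against Sv in soil. A family 61 hydrolase rose from 0.298 ± 0.261 to 54.6 ± 38.1 CPM (Sebve1_07465, log2 7.49 ± 0.70, n = 3 each). A family 11 xylanase (Sebve1_08875, log2 6.37 ± 1.01, 13 root reads) and a family 6 cellulase (Sebve1_00992, 209 ± 98.5 against 21 ± 4.34 CPM) rose. A hexose transporter rose from 4.98 ± 0.63 to 124 ± 58 CPM (Sebve1_09710, log2 4.69 ± 0.33), while another sugar transporter fell from 386 ± 19.2 to 49 ± 12.5 CPM (Sebve1_01919, log2 -2.94 ± 0.28). Glutathione transferases on 11 and 7 root reads (Sebve1_12373, log2 6.97 ± 1.02, and Sebve1_12376, log2 6.15 ± 1.09), an adhesin (Sebve1_12234, log2 6.4 ± 0.50) and a family 2 glycosyltransferase (Sebve1_09990, log2 5.44 ± 0.32) completed the 6 largest increases. These heat shock proteins, which keep other proteins folded, fell, HSP20 from 2290 ± 558 to 44.9 ± 13.2 CPM (Sebve1_04564, log2 -5.62 ± 0.33) and HSP104 from 2210 ± 873 to 85 ± 53.7 CPM (Sebve1_13077, log2 -4.74 ± 0.39). The 6 largest named decreases had 0 reads in the 3 Sv local libraries. A P-loop protein was at least 65.1-fold lower (Sebve1_06827) and translationally controlled tumour proteins at least 47.7-fold (Sebve1_14623) and 39.3-fold (Sebve1_12649). The other genes were an E-set protein at least 40.3-fold (Sebve1_00139), an anamorsin homologue at least 18.2-fold (Sebve1_13620) and an ABC transporter at least 15.8-fold (Sebve1_04946).

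Among 13410 tested Sv genes, 911 were higher and 1243 lower in roots than in soil, 733 and 1064 by at least 1 on the log2 scale. With RLE scaling the split was 1042 and 1029, and with DESeq2 1279 and 943, at a median shift of 0.1 in log2, so which direction held more genes is not settled. The total of 2154 was 1413 without Sv soil replicate 3 and 1411 without Sv local replicate 1, with 666 and 761 down. The decreases numbered 732 without Sv soil replicate 2 and 804 without Sv local replicate 2. Ribosomal proteins fell, with 53 of 62 down (54 down and 1 up adjusted over the list alone, camera adjusted p = 1.39e-30, adjusted p = 0.273 with an estimated correlation), at a median of -1.22, beyond that shift. Heat shock fell with 19 of 51 down and 3 up (26 and 3 adjusted over the list alone, adjusted p = 1.08e-06, and adjusted p = 0.273 with an estimated correlation). Carbohydrate-active enzymes rose, with 54 of 259 up and 7 down (57 and 10 alone, adjusted p = 2.9e-07, and adjusted p = 0.285 with an estimated correlation). Cytochromes P450 rose with 12 of 81 up and 2 down (12 and 2 alone, adjusted p = 0.000534, and adjusted p = 0.304 with an estimated correlation). MFS and ABC transporters were called up with 22 of 125 up and 8 down (25 and 9 alone, adjusted p = 0.00307, and adjusted p = 0.273 with an estimated correlation), with a median of 0.2 and a mean of -0.08. Nutrient transporters were not called (8 up and 5 down of 43, 10 and 5 alone, adjusted p = 0.0768).

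Bs on barley roots raised carbohydrate-active enzymes over Bs in soil, and with them single transporters and glutathione transferases. A family 7 cellulase was at 6230 ± 775 CPM in roots and 1.92 ± 0.167 in soil (Bipso1_00867, log2 11.65 ± 0.36, n = 3 each), and a family 61 hydrolase at 5080 ± 1620 against 0.798 ± 0.0813 CPM (Bipso1_05440, log2 12.61 ± 0.45). A family 43 hydrolase, of a family that acts on hemicellulose, rose from 4.01 ± 0.435 to 619 ± 33.3 CPM (Bipso1_06567). An ethanolamine utilization protein was at least 8880-fold higher in roots (Bipso1_02002, 402 ± 89.8 CPM against 0 reads) and the aldehyde dehydrogenase with the preceding identifier rose from 0.112 ± 0.12 to 1190 ± 171 CPM (Bipso1_02001, log2 13.30 ± 0.50). A methyltransferase was at least 2140-fold higher (Bipso1_11813), and a sterigmatocystin 8-O-methyltransferase-like gene was at 81.7 ± 51 CPM against 1 read (Bipso1_11830). Peptide synthetase Bipso1_12059, which fell in the soil mixture, rose in roots from 88.9 ± 46.5 to 1590 ± 114 CPM (log2 4.16 ± 0.41), and a prenyltransferase rose from 2.08 ± 1.6 to 296 ± 21.4 CPM (Bipso1_02670). Glutathione transferases (Bipso1_11815, log2 9.90 ± 0.57, and Bipso1_11836, log2 8.57 ± 0.43), an amino acid transporter (Bipso1_10064, log2 5.96 ± 0.44) and a ferric reductase, which serves iron uptake (Bipso1_09805, 458 ± 36.1 against 161 ± 20.9 CPM), rose.

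Lower in Bs on roots were the 30 kDa heat shock protein, at 10.9 ± 10.1 against 3600 ± 1350 CPM (Bipso1_08118, log2 -8.27 ± 0.60), and a WSC domain gene (Bipso1_09864, 19.2 ± 3.41 against 413 ± 65.5 CPM). Both Tar1p genes, whose yeast namesake lies within the ribosomal RNA repeat, had 0 reads in the 3 Bs local libraries and were at least 604-fold (Bipso1_12067) and 273-fold (Bipso1_06297) lower. A zinc knuckle gene (Bipso1_06486, at least 14.6-fold), a short-chain dehydrogenase (Bipso1_09272, at least 13.5-fold), a calcium ATPase (Bipso1_07688, at least 11.8-fold) and a cytochrome P450 (Bipso1_09269, at least 11-fold) had 0 reads there as well. Of 10510 tested Bs genes, 1694 were higher and 1493 lower, 1431 and 1104 by at least 1 on the log2 scale. Without Bs local replicate 1 or 3 the decreases numbered 978 and 987, and Bipso1_09269 lost its call. Kit and harvest day (6 in roots, 2 in soil) differed, so neither this nor the Sv comparison separates the root from them. Over the 9 root libraries inoculated with each fungus, 21 of 5594 Sv genes that soil levels predict to have at least 50 reads had at most 2% of them, and 27 of 6873 such Bs genes. The 30 kDa heat shock protein and all genes named above with 0 reads in Sv local or Bs local roots against soil are among them. Leaving out genes that take reads in samples without the fungus, as chosen after seeing the data, lost 29 of the 2154 Sv calls and 12 of the 3187 Bs calls.

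Carbohydrate-active enzymes were the only list of this comparison to hold with an estimated correlation, with 153 of 330 up and 47 down on roots (160 and 56 adjusted over the list alone, camera adjusted p = 2.95e-20, adjusted p = 0.00817 with an estimated correlation). Cytochromes P450 rose with 42 of 106 up and 9 down (46 and 11 adjusted over the list alone, adjusted p = 1.13e-06, and adjusted p = 0.172 with an estimated correlation). MFS and ABC transporters rose (60 up and 20 down of 204, 60 and 21 alone, adjusted p = 0.00422). Redox and detoxification rose (32 up and 8 down of 79, 36 and 11 alone, adjusted p = 0.00296), as did iron and siderophores (10 up and 1 down of 20, 12 and 3 alone, adjusted p = 0.0432). These 3 lists had an adjusted p = 0.236 with an estimated correlation. Nutrient transporters rose (23 up and 5 down of 69, 25 and 6 alone, adjusted p = 0.011, and adjusted p = 0.277 with an estimated correlation). Histones fell (7 of 12 down, 7 alone, adjusted p = 0.0432, and adjusted p = 0.451 with an estimated correlation). Ribosomal proteins (11 up and 1 down of 81), heat shock (10 up and 14 down of 49) and proteases (36 up and 29 down of 170) were not called. Neither were effector-like proteins (3 up and 5 down of 20), conidia and melanin (2 up and 2 down of 13) and zinc cluster factors (18 up and 9 down of 97). Secondary metabolism was not called with 14 up and 3 down of 49, at a median of 0.48 and a mean of -0.13.

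Within roots, Bs next to Sv raised a polyketide synthase and genes with neighbouring identifiers. A polyketide synthase rose from 43.5 ± 25.7 to 319 ± 178 CPM in co-inoculated against Bs local roots (Bipso1_02390, log2 2.74 ± 0.40, n = 3 each, adjusted p = 0.00262). With it rose a fitD-like gene (Bipso1_02395, log2 3.80 ± 0.64), a methyltransferase (Bipso1_02397, log2 3.6 ± 0.72), and a FAD-binding protein (Bipso1_02389, 523 ± 349 against 44 ± 32.9 CPM). So did a metallo-beta-lactamase (Bipso1_02391, log2 3.34 ± 0.42) and an ethD protein (Bipso1_02392, log2 3.19 ± 0.64). A versicolorin reductase, named after a step of aflatoxin synthesis (Bipso1_02400, 181 ± 113 against 18.4 ± 5.96 CPM), an MFS transporter (Bipso1_02404, log2 2.84 ± 0.54) and a cytochrome P450 (Bipso1_07860, log2 1.84 ± 0.38) rose too. Chosen after their values were seen, a geranylgeranyl diphosphate synthase (Bipso1_07859, log2 2.54 ± 0.49) and the hypothetical protein Bipso1_08486 rose, the latter from 29.8 ± 10.5 to 987 ± 581 CPM (log2 4.94 ± 0.45, adjusted p = 7.84e-05). Bipso1_08486 was at 0 CPM in all 3 Bs local libraries with Sv systemic, a difference from Bs local roots that edgeR did not call (adjusted p = 1). Without Bs local replicate 2 or 3 or co-inoculated replicate 3 the calls of Bipso1_02392, Bipso1_02397, Bipso1_02404, Bipso1_07859 and Bipso1_07860 ended, and without the last also those of Bipso1_02395 and Bipso1_02400. The 3 genes that fell were annotated as carbohydrate-active or cellulose-binding. They were Bipso1_08141 (72 ± 8.7 to 9.61 ± 3.67 CPM), the family 7 cellulase Bipso1_02639 (1850 ± 1530 to 407 ± 53.2 CPM, adjusted p = 0.0468) and the family 18 hydrolase Bipso1_04315 (309 ± 56.6 to 87.7 ± 45.1 CPM). The call of Bipso1_08141 ended without co-inoculated replicate 3, and that of Bipso1_04315 without replicate 2 or 3 of either group. That of Bipso1_02639 ended without Bs local replicate 2 (log2 -2.31) or 3 (log2 -1.28) and without co-inoculated replicate 1 (log2 -2.27), 2 (log2 -2.09) or 3 (log2 -2.21). It also ended with soil libraries in the fit (log2 -2.22), and without the genes that take reads in samples lacking Bs (log2 -2.18), an alternative chosen after seeing the data. In both, the fold was as large as before (log2 -2.17 ± 0.46), and over all alternatives the adjusted p ran from 9.46e-14 to 0.338.

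Of 4890 tested Bs genes, 20 rose and 3 fell in the co-inoculated roots. The count of 23 was 12 without Bs local replicate 2 or 3, 14 and 8 without co-inoculated replicates 2 and 3 (8 up and 0 down in the last), with 8 down instead of 3 without Bs local replicate 1. It was 70 without a filter on low counts, and 2 when all libraries inoculated with Bs, soil included, shared the fit. Secondary metabolism was called up with 1 of 23 members up (1 adjusted over the list alone, camera adjusted p = 0.00213, adjusted p = 0.154 with an estimated correlation). Cytochromes P450 were called up with 1 of 48 (2 alone, adjusted p = 0.0422, and adjusted p = 0.154 with an estimated correlation). Carbohydrate-active enzymes were called down with 2 of 220 down (4 down and 1 up alone, adjusted p = 0.0118, and adjusted p = 0.367 with an estimated correlation). With Sv on the opposite side edgeR called 0 Bs genes, DESeq2 0, and 111 had an unadjusted p under 0.05. Ribosomal proteins were called up with 0 of 67 members called (0 adjusted over the list alone, adjusted p = 0.0442, and adjusted p = 0.734 with an estimated correlation).

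**Figure D2:**
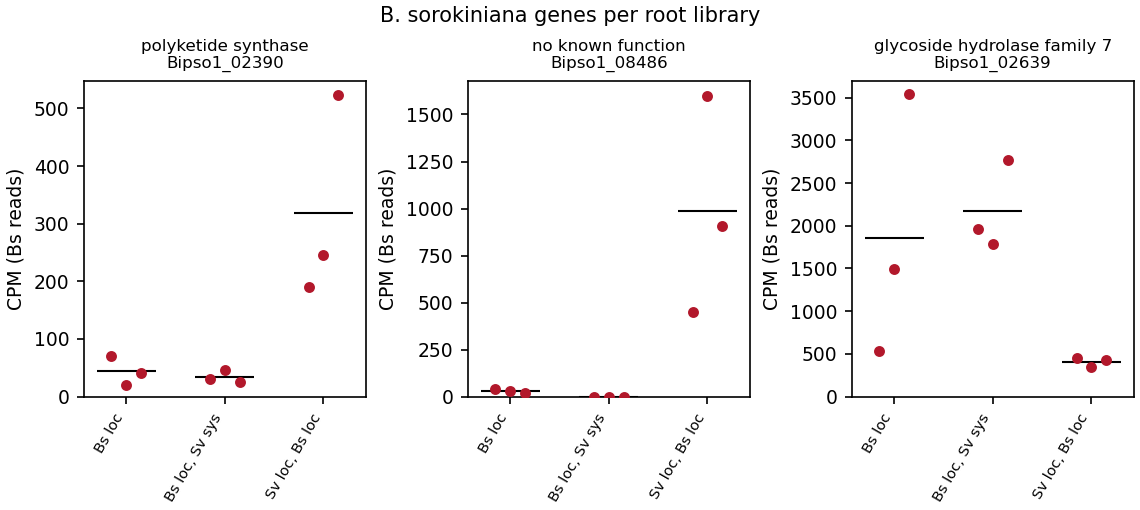
CPM of Bs reads for Bipso1_02390 (polyketide synthase), Bipso1_08486 (hypothetical protein) and Bipso1_02639 (family 7 cellulase) in Bs local, Bs local with Sv systemic, and co-inoculated roots; points are libraries and lines group means of 3. Bipso1_08486 lies at 987 ± 581 in co-inoculated against 29.8 ± 10.5 in Bs local roots, and at 0 in all 3 Bs local libraries with Sv systemic.

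Sv next to Bs in roots raised 2 genes of 3606 tested. Glutathione transferase Sebve1_12376 rose from 15.4 ± 7.43 to 216 ± 76.9 CPM (log2 3.64 ± 0.53, n = 3 each, adjusted p = 0.0145, on 75 reads against 7). The FAD/NAD(P)-binding protein Sebve1_00739 rose from 71.2 ± 12.2 to 298 ± 104 CPM (log2 2.09 ± 0.33, adjusted p = 0.0166). The count of 2 fell to 0 without Sv local replicate 1 or 3 or co-inoculated replicate 3, and to 1 without co-inoculated replicate 1 or 2. It was 0 when all libraries inoculated with Sv, soil included, shared the fit, and 51 without a filter on low counts. The redox list was called up with 1 of 26 (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.00714, adjusted p = 0.262 with an estimated correlation). Heat shock was called up with 0 of 24 called (0 alone, adjusted p = 0.0214, and adjusted p = 0.319 with an estimated correlation). With Bs on the opposite side edgeR called 0 Sv genes, DESeq2 0, and 283 had an unadjusted p under 0.05. In that comparison MFS and ABC transporters (48 tested) and nutrient transporters (23 tested) were called down and heat shock (24 tested) and ribosomal proteins (56 tested) up. In these 4 lists 0 members were called, also when adjusted over the list alone. Their adjusted p ran from 0.0158 to 0.0443, and from adjusted p = 0.357 to 0.679 with an estimated correlation.

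**Figure D3:**
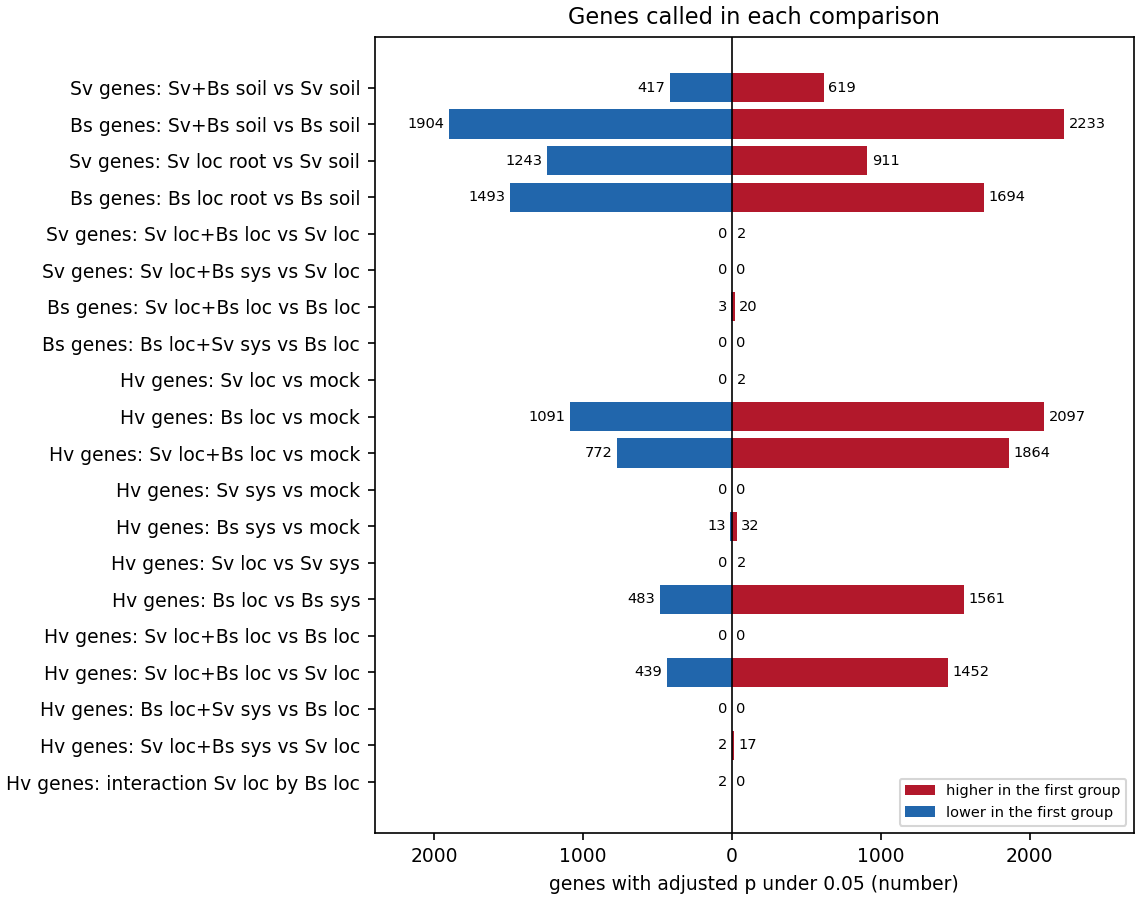
Number of genes higher (right) and lower (left) in the first group of each of 20 comparisons at an adjusted p of 0.05, with bars starting at 0. Bs in the soil mixture (2233 up, 1904 down) and barley with Bs local (2097 up, 1091 down) exceed barley with Sv local (2 up, 0 down) by far.

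Barley roots carrying Bs raised jasmonate genes and receptor kinases over mock roots and lowered aquaporins. Single genes of diterpenoid and lignin synthesis and of defence rose too, while the terpenoid list as a whole was not called. A syn-copalyl diphosphate synthase, which forms a precursor of labdane diterpenoids, rose from 51.8 ± 32.2 to 3330 ± 763 CPM (HORVU2Hr1G004620, log2 6 ± 0.57, n = 3 each, adjusted p = 2.31e-07). An ent-kaurene synthase-like gene (HORVU2Hr1G004540, 555 ± 136 against 11.9 ± 8.75 CPM) and a cytochrome P450 99A2-like gene (HORVU2Hr1G004600, 187 ± 38.2 against 2.98 ± 2.46 CPM) rose with it. Jasmonate methyltransferase, which forms methyl jasmonate, rose from 0.387 ± 0.67 to 173 ± 49.7 CPM (HORVU3Hr1G100190, log2 8.64 ± 0.71). TIFY10A, of the family that represses jasmonate signalling, rose from 14.3 ± 4.4 to 96.1 ± 26.4 CPM (HORVU5Hr1G062290). A subtilisin-like protease was at least 1360-fold higher (HORVU3Hr1G026270, 277 ± 248 CPM against 0 reads) and a caffeic acid O-methyltransferase, of lignin synthesis, at least 395-fold (HORVU4Hr1G001250). A laccase-25-like gene rose from 0.611 ± 0.203 to 406 ± 210 CPM (HORVU1Hr1G008360). The remaining largest increases were a resveratrol di-O-methyltransferase-like gene (HORVU1Hr1G089520, at least 255-fold), an aromatic amino acid decarboxylase-like gene (HORVU2Hr1G114390, at least 184-fold) and a premnaspirodiene oxygenase-like gene (HORVU5Hr1G063980, at least 150-fold). A PR1-like gene was at 230 ± 188 CPM against 2 reads in mock (HORVU5Hr1G106020).

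Pathogenesis-related protein PR10 rose from 0.675 ± 0.219 to 32.8 ± 4.71 CPM (HORVU0Hr1G011730, adjusted p = 2.76e-09) and a Bowman-Birk protease inhibitor from 24.4 ± 2.86 to 438 ± 212 CPM (HORVU1Hr1G065660). Cysteine-rich receptor-like kinase 2 rose from 0.27 ± 0.235 to 44.4 ± 13.8 CPM (HORVU3Hr1G002900), an LRR receptor kinase from 0.6 ± 0.378 to 194 ± 106 CPM (HORVU7Hr1G006940), and a WRKY factor by 3.20 ± 0.27 on the log2 scale (HORVU0Hr1G001430). Sugar transport protein 13 (HORVU4Hr1G067450, log2 2.78 ± 0.30) and a sulfate transporter (HORVU5Hr1G066360, log2 2.99 ± 0.29) rose. Water channels fell, PIP1-5 from 795 ± 32.2 to 310 ± 66.4 CPM (HORVU6Hr1G092960, log2 -1.36 ± 0.13) and PIP2-6 from 56.6 ± 3.64 to 12.7 ± 4.13 CPM (HORVU5Hr1G027240, log2 -2.15 ± 0.21). The largest named decreases were YSL6 genes, of the family that transports metal chelates (HORVU2Hr1G108400, log2 -5.43 ± 0.69, and HORVU0Hr1G017010, log2 -2.82 ± 0.75), and a nitrate transporter (HORVU7Hr1G098550, 3.35 ± 2.91 against 28.6 ± 11.4 CPM). The others were an extensin (HORVU1Hr1G086280, log2 -2.99 ± 0.64), a cytochrome P450 (HORVU0Hr1G005700, log2 -2.64 ± 0.77) and peroxidase 70 (HORVU7Hr1G026070, log2 -2.50 ± 0.70). Of 19693 tested genes, 2097 rose and 1091 fell, 1255 and 349 by at least 1 on the log2 scale. The total of 3188 was 1926 without Bs local replicate 1, with 1465 up and 461 down. The decreases numbered 677 without mock replicate 1, 694 without Bs local replicate 3 and 595 with only these 6 libraries fitted. The calls of HORVU0Hr1G017010, HORVU0Hr1G005700 and HORVU7Hr1G026070 ended without Bs local replicate 3.

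**Figure D4:**
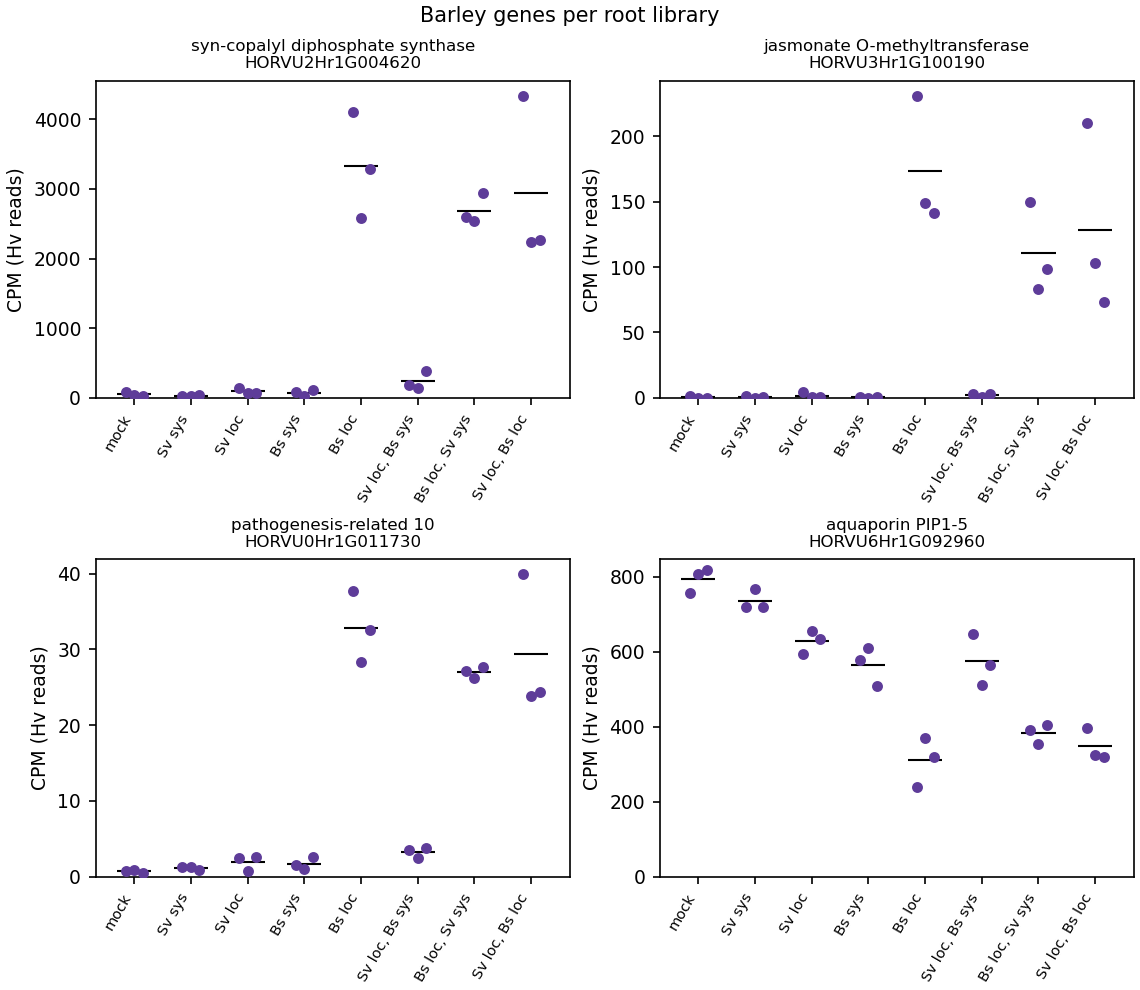
CPM of barley reads for syn-copalyl diphosphate synthase, jasmonate methyltransferase, PR10 and the water channel PIP1-5 in each root library by group; points are libraries and lines group means of 3. Syn-copalyl diphosphate synthase lies at 3330 ± 763 in Bs local and 2950 ± 1210 in co-inoculated roots, against 51.8 ± 32.2 in mock.

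In Bs local roots 3 barley lists held under both correlations. Receptor kinases had 88 of 240 up and 14 down (100 and 18 adjusted over the list alone, camera adjusted p = 8.76e-10) and jasmonate 21 of 45 up and 1 down (21 and 1 alone, adjusted p = 2.76e-06). Aquaporins had 9 of 21 down and 1 up (11 and 2 alone, adjusted p = 8.76e-10, median -1.13). Each of these lists had an adjusted p = 0.0289 with an estimated correlation. Glutathione transferases rose with 36 of 72 up and 2 down (38 and 3 adjusted over the list alone, adjusted p = 2.01e-09, and adjusted p = 0.162 with an estimated correlation). WRKY factors rose (21 up and 1 down of 65, 25 and 1 alone, adjusted p = 6.6e-06), as did cytochromes P450 (37 up and 8 down of 121, 39 and 15 alone, adjusted p = 3.95e-06). Defence proteins rose too (46 up and 14 down of 172, 51 and 19 alone, adjusted p = 0.00464), and these 3 lists had an adjusted p = 0.154 with an estimated correlation. Phenylpropanoid and lignin enzymes rose (39 up and 11 down of 125, 44 and 16 alone, adjusted p = 0.000227, and adjusted p = 0.164 with an estimated correlation). Cell wall genes fell (20 down and 4 up of 142, 28 and 5 alone, adjusted p = 1.22e-05, and adjusted p = 0.281 with an estimated correlation). Histones fell too (5 of 53 down, 1 alone, adjusted p = 9.67e-06, and adjusted p = 0.499 with an estimated correlation). Ribosomal proteins were called down at a median of -0.13 although 3 of 158 were called up and 0 down (0 alone, adjusted p = 0.0112, and adjusted p = 0.751 with an estimated correlation). NLR proteins (19 up and 14 down of 241) and ethylene (11 up and 3 down of 85) were not called. Neither were nutrient transport (6 up and 2 down of 36), sugar transport (10 up and 3 down of 55) and heat shock (4 up and 2 down of 53). Class III peroxidases were not called either (28 up and 18 down of 125, 29 and 34 adjusted over the list alone, median -0.55, mean 0.07), and terpenoid synthesis had 2 up and 2 down of 16 (median -0.18, mean 0.44).

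Co-inoculated roots raised syn-copalyl diphosphate synthase, jasmonate methyltransferase and PR10 over mock as well, in a comparison that shares its mock libraries with the previous one. The first was at 2950 ± 1210 CPM (HORVU2Hr1G004620, log2 5.83 ± 0.57, n = 3 each), the methyltransferase at 129 ± 72.1 CPM (HORVU3Hr1G100190, log2 8.21 ± 0.71) and PR10 up by 5.38 ± 0.36 (HORVU0Hr1G011730). The subtilisin-like protease was at least 577-fold higher (HORVU3Hr1G026270), the caffeic acid O-methyltransferase at least 229-fold (HORVU4Hr1G001250) and HORVU1Hr1G089520 at least 212-fold. Among water channels PIP2-6 fell (HORVU5Hr1G027240, log2 -1.91 ± 0.21) while the tonoplast channel TIP4-2 rose from 7.7 ± 3.99 to 74.8 ± 11.4 CPM (HORVU4Hr1G085250). YSL6 had 0 reads and was at least 55.9-fold lower (HORVU0Hr1G017010), and the nitrate transporter fell (HORVU7Hr1G098550, log2 -4.58 ± 0.57). In total 1864 genes rose and 772 fell, and the total of 2636 was 1278 when only these 6 libraries were fitted, with 1065 up and 213 down. The decreases numbered 467 without mock replicate 1, and 407 and 457 without co-inoculated replicates 2 and 3. Of 11 lists called, 0 held with an estimated correlation. Glutathione transferases had the smallest p, with 32 up and 1 down of 72 (37 and 4 adjusted over the list alone, adjusted p = 8.28e-09, and adjusted p = 0.168 with an estimated correlation). Defence proteins rose with 43 up and 6 down of 172 (47 and 6 alone, adjusted p = 0.00276, and adjusted p = 0.168 with an estimated correlation), while terpenoid synthesis was not called (2 up and 2 down of 16). Receptor kinases rose with 79 up and 3 down of 240 (90 and 11 alone, adjusted p = 2.26e-08) and jasmonate with 18 up and 3 down of 45 (20 and 5 alone, adjusted p = 1.67e-05). Aquaporins fell with 10 down and 2 up of 21 (11 and 2 alone, adjusted p = 2.26e-08). The last 3 lists had an adjusted p = 0.0542 with an estimated correlation.

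Set against the opposite, uninoculated side of Bs plants, Bs local roots raised receptor kinases and jasmonate genes and lowered aquaporins. Both sides may be of the same plants, and the fit did not pair them. Ascorbate oxidase was at least 372-fold higher (HORVU5Hr1G076510), jasmonate methyltransferase rose by 8.83 ± 0.72 on the log2 scale (HORVU3Hr1G100190), and syn-copalyl diphosphate synthase was at 3330 ± 763 against 72.9 ± 43 CPM (HORVU2Hr1G004620, log2 5.51 ± 0.56, n = 3 each). PR10 (HORVU0Hr1G011730, log2 4.25 ± 0.31) and cysteine-rich receptor-like kinase 2 (HORVU3Hr1G002900, log2 4.81 ± 0.36) rose. An indole-2-monooxygenase-like gene, of the benzoxazinoid pathway, fell from 67.3 ± 21 to 6.32 ± 4.46 CPM (HORVU1Hr1G021680). A defensin (HORVU1Hr1G002100, log2 -3.11 ± 0.94), a purple acid phosphatase (HORVU1Hr1G004650, log2 -2.64 ± 0.68) and PIP1-5 (HORVU5Hr1G055200, log2 -1.38 ± 0.20) fell. In total 1561 genes rose and 483 fell, and the total of 2044 was 1276 without Bs local replicate 1, with 182 down. The decreases numbered 314 and 289 without Bs systemic replicates 2 and 3, and without either the calls of the defensin and the purple acid phosphatase ended, as they did without Bs local replicate 3. Of 11 lists called, 3 held with an estimated correlation. Receptor kinases (88 up and 7 down of 240, 102 and 13 adjusted over the list alone, adjusted p = 8.11e-14, and adjusted p = 0.0105 with an estimated correlation) and jasmonate (15 up and 2 down of 45, 22 and 3 alone, adjusted p = 2.01e-06) rose. Aquaporins fell with 11 of 21 down (12 alone, adjusted p = 2.45e-10), and they and jasmonate each had an adjusted p = 0.0222 with an estimated correlation. Defence proteins rose with 41 up and 9 down of 172 (46 and 13 alone, adjusted p = 0.000729, and adjusted p = 0.124 with an estimated correlation), and terpenoid synthesis was not called (2 up and 1 down of 16).

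Co-inoculated roots, the same libraries as those set against mock, raised PR1 (HORVU5Hr1G055950, at least 352-fold), the PDR4 transporter (HORVU3Hr1G071470, at least 180-fold), PR10 (HORVU0Hr1G011730, log2 3.91 ± 0.31) and syn-copalyl diphosphate synthase (HORVU2Hr1G004620, 2950 ± 1210 against 93.1 ± 43.1 CPM, log2 4.99 ± 0.54, n = 3 each) over Sv local roots. LHY, a clock factor that peaks at dawn, fell from 217 ± 66.4 to 48.5 ± 21.6 CPM (HORVU7Hr1G070870, log2 -2.16 ± 0.45). An RCC1 gene (HORVU3Hr1G085860, log2 -3.26 ± 0.62) and a SEN102-like gene (HORVU3Hr1G088080, log2 -2.18 ± 0.43) fell as well. In total 1452 genes rose and 439 fell, and the total of 1891 was 1177 and 1221 without Sv local replicates 1 and 3. The decreases numbered 228, 244 and 231 without Sv local replicates 1, 2 and 3, and 218 and 275 without co-inoculated replicates 2 and 3. Of 11 lists called, 1 held with an estimated correlation. Receptor kinases rose with 76 up and 5 down of 240 (90 and 10 adjusted over the list alone, adjusted p = 1.29e-10, and adjusted p = 0.0381 with an estimated correlation). Histones fell with 14 of 53 down (30 alone, adjusted p = 1.61e-14, and adjusted p = 0.182 with an estimated correlation), among them an H2A (HORVU6Hr1G021260, log2 -0.82 ± 0.15) and an H1 (HORVU2Hr1G094390, log2 -0.61 ± 0.13).

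Adding Sv to Bs on the same side changed no barley gene past the threshold. Against Bs local roots edgeR called 0 genes in co-inoculated roots, DESeq2 1, and 745 had an unadjusted p under 0.05. With n = 3 per group, syn-copalyl diphosphate synthase was at 2950 ± 1210 against 3330 ± 763 CPM (HORVU2Hr1G004620) and jasmonate methyltransferase at 129 ± 72.1 against 173 ± 49.7 CPM (HORVU3Hr1G100190), both within the spread between replicates. As lists, phenylpropanoid and lignin enzymes, receptor kinases and class III peroxidases were called down and aquaporins up, with 0 members called, also when adjusted over the list alone. Their adjusted p ran from 0.000439 to 0.0244, and from adjusted p = 0.369 to 0.69 with an estimated correlation. With Sv on the opposite side of Bs local roots edgeR again called 0, DESeq2 1, and 1173 had an unadjusted p under 0.05. There ribosomal proteins, histones, cell wall genes, aquaporins and class III peroxidases were called up and receptor kinases and WRKY factors down, with 0 members of any list called, also when adjusted over the list alone. Their adjusted p ran from 7.4e-20 for ribosomal proteins to 0.0262, and from adjusted p = 0.413 to 0.711 with an estimated correlation.

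Whether Bs acted differently on barley with Sv was tested as an interaction over mock, Sv local, Bs local and co-inoculated roots. A germin-like protein 8-5 had a smaller fold rise with Bs where Sv was present (HORVU0Hr1G009400, log2 -3.45 ± 0.55, adjusted p = 0.0341). It lay at 1.61 ± 0.653, 11.4 ± 3.61, 218 ± 88.7 and 137 ± 27.8 CPM in these groups (n = 3 each). Neither Sv local against mock nor co-inoculated against Bs local called it. HORVU1Hr1G049400, chosen after its values were seen, was the other gene called (fitted log2 -9.4, no bound since mock held 0 reads, adjusted p = 0.00651). DESeq2 called 7, 1 up and 6 down, and 693 had an unadjusted p under 0.05 in edgeR. The count of 2 fell to 0 without mock replicate 1 or with only these groups fitted, and to 1 without mock replicate 2 or 3, Sv local replicate 1 or 3, or co-inoculated replicate 2 or 3. Histones, phenylpropanoid and lignin enzymes, cytochromes P450, glutathione transferases and jasmonate were called down and aquaporins up, with 0 members called, also when adjusted over the list alone. Their adjusted p ran from 0.00419 to 0.0163, and from adjusted p = 0.537 to 0.692 with an estimated correlation.

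Sv local roots differed from mock roots in 2 genes. HORVU1Hr1G032830, annotated as a transcription factor, rose from 0.35 ± 0.323 to 12.9 ± 4.66 CPM (log2 5.13 ± 0.70, n = 3 each, adjusted p = 0.00417). HORVU1Hr1G049400, chosen after its values were seen, was at least 117-fold higher (23.8 ± 7.03 CPM against 0 reads, adjusted p = 0.000225), and its annotation is a hypothetical protein named after a fungal locus. Both were also the calls of Sv local against the systemic side of Sv plants (log2 4.83 ± 0.69, adjusted p = 0.00673, and log2 6.25 ± 0.70, adjusted p = 0.000774). Over all 24 root libraries HORVU1Hr1G049400 had 5 reads in the 9 without a fungus on the sampled side and 1685 in the 15 with one, and HORVU1Hr1G032830 had 17 and 747. Against mock, 804 genes had an unadjusted p under 0.05, and DESeq2 called 18, 12 up and 6 down. The count of 2 was 1 without mock replicate 1 or 2 or with only these groups fitted and 12 without a filter on low counts. Against the systemic side it was 1 without Sv systemic replicate 1 or 2 or Sv local replicate 1, or with only these groups fitted, 6 without a filter and 4 with DESeq2. Histones were called up against mock (adjusted p = 4.69e-05, and adjusted p = 0.827 with an estimated correlation). Aquaporins were called down against the systemic side (adjusted p = 0.0171, and adjusted p = 0.949 with an estimated correlation). Both lists had 0 members called, also when adjusted over the list alone.

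On the systemic side of Sv plants edgeR called 0 genes against mock, DESeq2 5, and 689 had an unadjusted p under 0.05. Without a filter on low counts edgeR called 3. Histones were called up and NLR and heat shock proteins down, with 0 members called, also when adjusted over the list alone. Their adjusted p ran from 0.00104 to 0.0447, and from adjusted p = 0.0817 to 0.864 with an estimated correlation.

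On the systemic side of Bs plants the genes that moved included clock genes. LUX, an evening gene of the plant clock, rose from 3.88 ± 0.703 to 31.1 ± 11.6 CPM (HORVU3Hr1G114970, log2 2.99 ± 0.40, n = 3 each, adjusted p = 0.000582). An LNK4-like gene, of a family of morning genes, fell from 18.5 ± 10.3 to 2.89 ± 1.87 CPM (HORVU3Hr1G040870). TIP4-2 rose from 7.7 ± 3.99 to 66.1 ± 16.7 CPM (HORVU4Hr1G085250, adjusted p = 7.36e-06) and a polyglutamine-binding protein by 3.11 ± 0.43 on the log2 scale (HORVU2Hr1G099330). YSL6 fell from 14.9 ± 7.9 to 0.492 ± 0.675 CPM (HORVU2Hr1G108400) and the nitrate transporter from 28.6 ± 11.4 to 4.16 ± 2.65 CPM (HORVU7Hr1G098550). In total 32 genes rose and 13 fell, 22 and 9 by at least 1 on the log2 scale. The count of 45 was 21 and 26 without mock replicates 2 and 3 (4 and 3 down), and 24 and 25 without Bs systemic replicates 1 and 2 (4 and 3 down), with 20 down without mock replicate 1. Without mock replicate 2 or Bs systemic replicate 1 or 2 the calls of the LNK4-like gene and the nitrate transporter ended. The count was 16 with only these groups fitted, 105 with DESeq2 and 90 without a filter. Class III peroxidases (adjusted p = 2.02e-05) and cell wall genes (adjusted p = 0.0233) were called down and glutathione transferases up (adjusted p = 0.034), each with an adjusted p = 0.616 with an estimated correlation. In each of them 0 members were called, also when adjusted over the list alone.

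With Bs opposite Sv local roots, 3 of 9 clock genes indexed below moved. LHY fell from 217 ± 66.4 to 32.8 ± 3.4 CPM (HORVU7Hr1G070870, log2 -2.72 ± 0.47, n = 3 each), and LUX rose from 9.81 ± 1.85 to 63.6 ± 4.94 CPM (HORVU3Hr1G114970, log2 2.70 ± 0.35). A REVEILLE 7-like gene (HORVU2Hr1G104580, log2 2.84 ± 0.53), HORVU2Hr1G099330 (log2 2.43 ± 0.39), TIP4-2 (HORVU4Hr1G085250, 86.4 ± 12.5 against 17.5 ± 4.54 CPM) and a SWEET14-like sugar transporter (HORVU6Hr1G000440, 222 ± 105 against 52.2 ± 9.17 CPM) rose. Chosen after their values were seen, the evening gene TOC1 (HORVU6Hr1G057630, log2 0.82 ± 0.13) and CONSTANS-LIKE 9 (HORVU6Hr1G071950, log2 1.89 ± 0.28) rose. In all 17 genes rose and 2 fell, and DESeq2 called 34 (21 up, 13 down). The count of 19 was 5 and 2 without Sv local replicates 2 and 3, 12, 6 and 11 without replicates 1, 2 and 3 of Sv local with Bs systemic, and 33 without a filter. Without Sv local replicate 2 or 3 or the other group's replicate 2 the calls of LHY, TOC1, the SWEET14-like, the REVEILLE 7-like and the HORVU2Hr1G099330 genes ended, and without Sv local replicate 3 that of CONSTANS-LIKE 9, while LUX kept its call in all alternatives. Histones were called down (adjusted p = 1.55e-05, and adjusted p = 0.934 with an estimated correlation) with 0 members called, also when adjusted over the list alone. Of the 45 and 19 genes of both comparisons, which share 1 fit, 12 moved the same way in both. Different harvest hours could give these shifts too.

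A clock index, chosen after the data were seen, took the mean log2 level of 3 morning genes minus that of 6 evening genes, with mock at 0 ± 0.68. It was -1.37 ± 0.68 in Sv systemic and -1.69 ± 0.48 in Sv local roots, -3.15 ± 0.79 in Bs systemic and -2.77 ± 0.77 in Bs local roots. It was -3.87 ± 0.36 in co-inoculated, -4.01 ± 0.05 in Sv local with Bs systemic and -4.16 ± 0.03 in Bs local with Sv systemic roots. All 7 differences are from the same 3 mock libraries, and the genes were picked because some of them had moved, so no test of the index is given. LHY, the LNK4-like gene and LUX carried most of it, while the gigantea genes hardly differed from mock in some groups (0.02 and 0.12 in log2 in Bs local with Sv systemic roots).

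**Figure D5:**
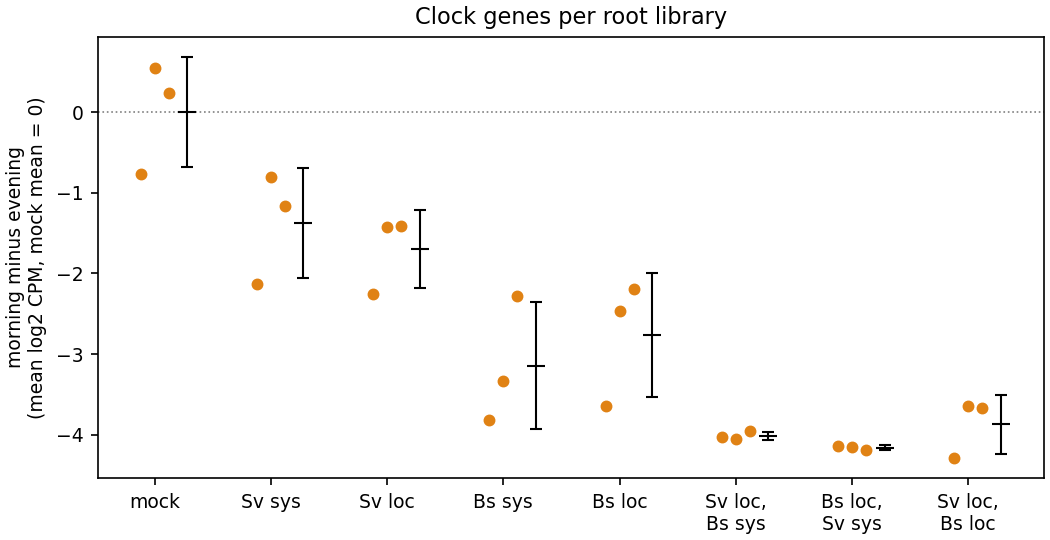
Clock index per root library, the mean log2 CPM of 3 morning genes minus that of 6 evening genes, set to 0 at the mock mean; points are libraries and bars group mean ± SD of 3. Bs systemic roots lie at -3.15 ± 0.79 and Sv local with Bs systemic roots at -4.01 ± 0.05.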

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

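All tests in this part were chosen only after the results they address had been seen, and so were the members of the clock list and its bounds, the rules on contact and harvest time, the choice of Sv systemic roots for the plant-wide explanation, the limits of 50 reads, 2% and 0.5 to 2 times the predicted reads, and the choice of the 2 barley genes. The rule on shared annotation was revised several times after its values were known.

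The difference between groups tested as an interaction came out for germin-like protein 8-5 (HORVU0Hr1G009400, log2 -3.45) and for HORVU1Hr1G049400 (fitted log2 -9.4). Signal outside the main measurement appeared as Sv reads in Bs soil, at 0.197% of reads (0.132 to 0.24%), and as Bs reads in Sv soil, at 0.455% (0.404 to 0.491%). In mock roots the background was 0.0299% and 0.0646%. The 12 genes with most such reads held 88.6% of the Sv and 91.1% of the Bs background in roots, and 50.7% and 69.4% in soil. Across genes, which are not independent replicates, the background in soil ran with the fungus' own soil profile at a Spearman rho of 0.827 for Sv and 0.895 for Bs.

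Some barley clock genes shifted with treatment (gigantea hardly in some groups), on a list not tested against other genes. Contact of the sampled side with Bs is argued against for LHY, LUX and TOC1, called in both comparisons with Bs only opposite. LUX alone kept both calls in all alternatives (adjusted p = 0.000582 and 0.00152). In Bs systemic roots alone the same holds for adagio 3 (log2 1.63) and the LNK4-like gene (log2 -2.66). It stays open for the rest. Harvest at different hours per treatment stays open, as the labels give none. So does a plant-wide response to the fungi, with -1.37 ± 0.68 in Sv systemic roots. Either could give both sides a like index, as with Bs (-2.77, -3.15) and with fungi opposite (-4.16, -4.01 ± 0.05).

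Some fungal genes read in soil were almost absent from the 9 root libraries inoculated with each fungus. They were 21 of 5594 in Sv with 124 root reads in total and 27 of 6873 in Bs with 77. The set holds only genes for which soil levels predict at least 59.2 (Sv) and 51.8 (Bs) reads at the root depth, so counting error is left out by its definition rather than by a test. Reads split between near-identical copies stay open in both. In Sv 8 of the 16 genes with annotation text shared it with another of the set (random sets 0.219 on average, permutation p = 1e-04, the smallest possible), in Bs 2 of 15 (0.0972, permutation p = 0.05), and with hypothetical proteins counted in, 8 of 21 and 6 of 27 (0.184 and 0.252, permutation p = 1e-04 and 2e-04), but shared text is only a proxy for sequence and does not say why soil and root would differ. Silence of these genes in roots could not be told apart from kit or harvest day, which differ between root and soil, and none was tested.

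The 2 barley genes called in Sv local roots had reads mainly on sides that held a fungus. Fungal reads counted to barley may be their source. Scaling single-fungus roots by fungal reads predicted 432 reads of HORVU1Hr1G049400 in co-inoculated roots and 453 were found, a ratio of 1.05 (0.79 to 1.8 over 9 libraries), and for HORVU1Hr1G032830 198 and 230, a ratio of 1.16 (0.839 to 1.86). A barley response to either fungus that follows fungal load stays open, since only 5 reads of HORVU1Hr1G049400 lay on the 9 sides without a fungus, which such a response would also give. The calls of Sv local roots against mock, those against the systemic side, and 1 of the 2 interaction calls rest on these genes.

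Other splits of the 6 libraries of a comparison, fitted alone, number 10 with the real one, too few for a share under 0.05. The real split and the highest of the others called 1036 and 0 Sv genes in soil, 2154 and 0 Sv genes between roots and soil, 2 and 0 Sv genes in co-inoculated roots, 4137 and 0 Bs genes in soil, 3187 and 0 Bs genes between roots and soil, 17 and 0 Bs genes in co-inoculated roots, and 0 and 1 Bs genes with Sv opposite. For barley they were 2199 and 0 in Bs local, 1278 and 0 in co-inoculated and 16 and 1 in Bs systemic roots against mock. They were 1 and 1 in Sv local against Sv systemic, 2064 and 0 in Bs local against Bs systemic, 1758 and 0 in co-inoculated against Sv local, and 14 and 0 in Sv local roots with Bs opposite. Against Bs local both co-inoculated roots and those with Sv opposite gave 0 and 0. In Sv local against mock 2 of the 10 splits reached the real count, in Sv local against Sv systemic 3. Where the real split called 0 genes, all 10 reach it by construction, which tests nothing. Some other splits called more genes than the real one, 25 against 0 for Sv with Bs opposite, 7 against 1 for barley in Sv local and 4 against 0 in Sv systemic roots. This points to a structure of those samples beyond their groups, whose nature was not tested. For the interaction the 12 libraries fitted alone gave 0 calls, a count that all 30 regroupings reach by construction (highest 1), so the regroupings test nothing there.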

How the results depend on the processing

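All alternatives here were planned except the removal of genes that take reads in samples lacking the fungus, which was chosen after seeing the data and lost 4, 3, 29 and 12 calls of Sv soil, Bs soil, Sv roots against soil and Bs roots against soil, 1 of the 23 of Bs in co-inoculated roots and 0 of the other fungal comparisons between roots. Of these lost calls 1, 0, 8, 6 and 0 were of the removed genes themselves. No named gene reversed direction under any alternative that gave it an adjusted p, but many lost their call. Counting each named gene once per alternative, calls were lost in 72 of 362 cases for Sv and 2 of 449 for Bs in soil, 22 of 397 and 3 of 465 in roots against soil, and 10 of 24 and 74 of 276 in co-inoculated roots. For barley they were lost in 3 of 22 (Sv local), 19 of 517 (Bs local), 19 of 451 (co-inoculated) and 10 of 66 (Bs systemic) against mock, 4 of 22 and 29 of 439 between local and systemic sides of Sv and Bs plants, 15 of 451 in co-inoculated against Sv local, 80 of 209 in Sv local with Bs opposite and 10 of 34 for the interaction. Where a count moved by over 1.5 times the cause was not tested unless fewer libraries were fitted. DESeq2 called 2561 genes for Sv in soil, and for barley 18 in Sv local, 5 in Sv systemic, 105 in Bs systemic, 4 in Sv local against Sv systemic, 1 in co-inoculated against Bs local, 1 in Bs local with Sv opposite, 34 in Sv local with Bs opposite and 7 for the interaction. Without a filter on low counts the counts were 51 and 48 for Sv in roots with Bs local and systemic, 70 and 5 for Bs with Sv local and systemic, and for barley 12 in Sv local, 3 in Sv systemic, 90 in Bs systemic, 6 in Sv local against Sv systemic and 33 in Sv local with Bs opposite. With all libraries of the fungus in the fit, Sv in co-inoculated roots had 0 calls and Bs 2. With only the compared groups fitted, barley had 1 in Sv local, 1278 in co-inoculated and 16 in Bs systemic roots against mock, 1 in Sv local against Sv systemic and 0 for the interaction. Other totals stayed within 1.5 times, but some counts of decreases did not. The split of Sv in roots against soil, given above for RLE and DESeq2, was 903 up and 799 down with all Sv libraries (median shift 0.11 in log2). That fit also shifted the median of Bs in soil by 0.11. Per 100 reads of the other fungus, Bs in the mixture stood at 38.

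A block for replicate number, as if equal numbers were pairs, gave 1 call for Sv with Bs opposite, and for barley 10 in Sv local, 4 in Sv systemic, 137 in Bs systemic, 2956 in co-inoculated against Sv local, 2 in Bs local with Sv opposite and 53 in Sv local with Bs opposite. In the block fit 4 list calls were lost, MFS and ABC transporters and cytochromes P450 of Bs in soil (adjusted p = 0.0583 each), histones of Sv in soil (adjusted p = 0.0737) and cytochromes P450 of Bs in co-inoculated roots (adjusted p = 0.0523), and 13 were gained. The labels do not pair the numbers. As a hint from the data, 24 of 24 barley libraries correlated best with libraries of their own number and 65 of 84 pairs exceeded 0.1 (-0.09 to 0.61), in Bs roots 9 of 9 libraries and 7 of 9 pairs, in Sv roots 6 of 9 and 4 of 9, and in the soil fits at most 1 of 3 pairs.

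With each library left out in turn, calls ranged from 28 to 1569 (Sv soil), 2315 to 4606 (Bs soil), 1411 to 1870 (Sv roots against soil), 2287 to 2762 (Bs roots against soil), 0 to 3 and 0 to 0 (Sv in roots with Bs local and systemic), and 8 to 30 and 0 to 0 (Bs with Sv local and systemic). For barley they ranged from 1 to 2 (Sv local), 1926 to 3074 (Bs local), 1829 to 2546 (co-inoculated), 0 to 2 (Sv systemic) and 21 to 46 (Bs systemic) against mock. The other ranges were 1 to 3 (Sv local against Sv systemic), 1276 to 2016 (Bs local against Bs systemic), 0 to 2 (co-inoculated against Bs local), 1177 to 1542 (co-inoculated against Sv local), 0 to 0 (Bs local with Sv opposite), 2 to 13 (Sv local with Bs opposite) and 0 to 2 (interaction). The log2 difference in Bs share ranged from -1.42 to -0.78 in co-inoculated roots and from -1.14 to -0.24 with Sv opposite. That of the Sv share ranged from -0.73 to 0.07 with Bs local and from -0.51 to 0.07 with Bs systemic, turning at 0.07, 0.01, 0 and 0.07 without single libraries, and the Bs share of the soil mixture from 24.2 to 29.1%. Fungal depth in roots limits each comparison that uses it, and 2-fold changes of simulated genes were called for 16% (Sv) and 11% (Bs) in roots against soil and for 29% and 42% between roots.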

Other observations

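The test in this part was chosen only after the result was seen, from a run of identifiers noticed among the calls.

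Bs genes that rose in co-inoculated roots clustered by identifier. Besides the polyketide synthase and its named neighbours, the genes chosen after their values were seen include a mannitol-1-phosphate dehydrogenase (Bipso1_02402, log2 3.04 ± 0.40), a questin oxidase-like gene (Bipso1_02393, log2 2.50 ± 0.43), Bipso1_02388 (log2 2.14 ± 0.38) and, outside the run, an idi-2 gene (Bipso1_01960, 1970 ± 588 against 444 ± 197 CPM, log2 2.13 ± 0.34, n = 3 each). Calls spread at random over the identifiers are argued against. Of the 20 genes called higher, 11 lay within a window of 20 identifiers, and all 11 genes tested in that window were called higher, while the highest of 10000 random sets had 4 (permutation p = 1e-04, the smallest possible). All 11 were higher under each alternative run (lowest log2 1.47), but in some fewer were called, 9 with DESeq2, 7 and 6 without Bs local replicates 2 and 3, 8 and 4 without co-inoculated replicates 2 and 3, and 1 with soil libraries in the fit. A hypothesis from this is that these genes may form a gene cluster switched on next to Sv, with 11 as the value that prompted it. Identifiers are not coordinates, and no genome was used here, so their order on a chromosome was not tested.

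Replicates differed from each other by more than sampling noise in every group, with a lowest chi-square per degree of freedom of 1.82 for any pair of libraries.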
